A study of Homo sapiens with 6 samples.

How the data were processed

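SKOV3, an established human ovarian carcinoma line, had received an siRNA against HJURP or a negative control siRNA (NC). Per the labels' protocols, total RNA was extracted with Trizol 24 h later and libraries were made with a NEBNext Ultra RNA kit. There were 3 libraries per group, called siHJURP replicates 1 to 3 and NC replicates 1 to 3. The design text speaks of triplicates of more than one kind, so it is unclear whether the replicates came from separate cultures. The p-values therefore measure the spread between these samples, which may be partly technical. The siRNA sequences, a selection step for the RNA and a sequencing batch were not given in the sources used here.

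The authors' deposited values are FPKM (fragments scaled by gene length and library size), in 1 table per library. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build hg38 were used. Whether the counting used strand was not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical copies, can therefore not be told apart. Each table listed 58735 genes, all of them found in the GENCODE 29 annotation and 58724 of them with the same start and end. Biotypes, transcripts and 3′ UTR sequences were taken from that annotation.

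How the FPKM had been scaled was not given either, so it was worked out from the values. FPKM multiplied by gene length came to whole multiples of what 1 read is worth in 100% of the values of each library, within a tolerance of 0.01 reads. The whole reads summed to 17304428, 17625638 and 17116487 in NC replicates 1, 2 and 3. They summed to 17672607, 18027065 and 17524772 in siHJURP replicates 1, 2 and 3. The library size behind the deposited FPKM was 0.985 to 0.989 times these sums in NC and 1.02 to 1.03 times in siHJURP, so a scaling between libraries was already in the deposited values. Rescaling by the median ratio called the same 5068 genes. At this depth HJURP had 595 to 608 reads in each siHJURP library, whereas a short gene near 1 FPKM can rest on a few reads.

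Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 13365 in all, of which 10875 were protein-coding. The values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with moderated statistics, an intensity trend and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of low genes. HJURP was also compared by an exact permutation test, two-sided like the other tests. Unless another test is named, the adjusted p-values of single genes are from this limma fit. Of 33 gene lists, 32 had at least 5 tested members and were compared with all other genes by limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. They were tested again with an estimated correlation and with fry, limma's rotation test of each list by itself. The remaining list, markers of other cell types, had 1 tested member.

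The comparison, the lists, the test and the rule for named genes were fixed before the data were examined. The rule takes HJURP, then the 12 highest and 12 lowest fold changes among called genes with a symbol whose groups did not overlap. It adds up to 4 members of each described list by adjusted p, and fixed genes (CENPA, WEE1, CHEK1, CDKN1A, MYC, CCNB1, CCND1, ERBB2 and MKI67 among them). Some of the genes that the rule takes, and 1 of the lists, are not reported here. The other genes of the rule, not all of them named in the text, number 142, of which 39 overlap another tested gene, IFIT1, OGFR, ZNF664, HABP4, VIM, CCND1, CENPA, CHEK1, ERBB2, FEN1, COL4A1, KRT8 and KRT18 among them.

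The alternatives were 2 other pseudocounts, 2 other filters, TPM, median-ratio and quantile scaling, limma without a trend, with robust moderation or with array weights, and a replicate block. Protein-coding genes alone and each library left out in turn completed the planned set. Alternatives chosen after seeing the data were limma's voom on the whole reads, each library's own read total, genes of at least 200 bases, siHJURP replicates 1 and 3 both left out, and genes with certain 7-base sequences in the 3′ UTR left out. Those sequences came from a scan of all 16384 7-mers in the longest annotated 3′ UTR of 10835 protein-coding genes. It related each 7-mer to the rank of the fold change after correction for the length and the A and T share of the UTR. The scan was repeated on the odd-numbered chromosomes with X and on the even-numbered ones, so that sequences picked in one set were tested on the genes of the other. The scan used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and medians were compared by permutation tests with 100000 resamples. These tests shuffled genes and treat them as independent, so their p-values do not measure the spread between libraries. Families of genes that share the stem of their symbol were compared by camera, also after the data were seen.

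The limma fit was tested on simulated data for the comparison of siHJURP with NC. Negative binomial reads for the 13365 genes were drawn at each gene's mean over the 6 libraries and the real library sizes, with an assumed dispersion of 0.005 and 200 changed genes. The fit recovered 5 of 50 genes changed 1.25-fold, 32 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 48 of 50 changed 4-fold. It called 12 of 13165 unchanged genes. Far fewer genes changed in the simulation than were called in the data (37.9% of those tested), so the recovery in the data may differ. Camera recovered the 1 planted list and called 0 of the 31 others. The simulated genes varied independently, so this does not show how camera at the preset correlation acts on correlated lists. In the data the interferon list had an estimated correlation of 0.933, and camera called up to 12 lists in splits that mixed the groups. Each of those splits divided the siHJURP libraries unevenly, so part of their difference from NC remained. Those calls are therefore not a count of false calls. In permuted fold changes with a planted shift, the scan ranked the planted 7-mer first.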

Results

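Gene expression was measured by RNA-seq in SKOV3 ovarian carcinoma cells 24 h after treatment with a small interfering RNA (siRNA, a short duplex that directs the breakdown of a matching transcript) against HJURP, or with a negative control siRNA (NC). HJURP is the chaperone that places the histone variant CENPA at centromeres. Each group had 3 libraries, with 17116487 to 17625638 reads in genes in NC and 17524772 to 18027065 in siHJURP. Between 26788 and 27259 genes had a value above 0 per library, and MT-CO1 was the highest gene in each. The correlation of log2(FPKM + 1) was 0.984 to 0.987 within a group and 0.964 to 0.971 between groups, and the first principal component held 56.2% of the variance. No pair of libraries held identical values.

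The first comparison asked how far HJURP itself was silenced. HJURP (ENSG00000123485, chromosome 2, 233833416 to 233854566 in hg38) had 29.4 ± 0.51 FPKM in NC and 8.65 ± 0.010 in siHJURP (mean ± SD, n = 3 per group here and below). This was 70.6% lower, a log2 fold change of -1.66 (SE 0.034, limma adjusted p = 1.41e-06). The libraries held 1912, 1930 and 1932 reads of HJURP in NC and 600, 608 and 595 in siHJURP. The exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. CENPA, the histone that HJURP carries, had 13.9 ± 1.3 FPKM in NC and 13.5 ± 1.3 in siHJURP and did not pass the test (log2 -0.03, SE 0.088, limma adjusted p = 0.806). The sign of this small difference turned under TPM, quantile and total-read scaling.

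The main comparison asked which genes changed with HJURP silencing. The lowest was H2AFX (ENSG00000188486, chromosome 11), which encodes the histone variant phosphorylated at DNA breaks. It fell from 163.6 ± 5.5 to 25.4 ± 2.2 FPKM, 6.45-fold lower (log2 -2.64, SE 0.063, adjusted p = 2.21e-06). The calcium-binding S100A16 fell from 453.8 ± 6.3 to 92.2 ± 3.5 FPKM (log2 -2.29). PLAU, the urokinase plasminogen activator, fell from 133 ± 1.4 to 33.8 ± 1.2 FPKM (log2 -1.95), and VIM, the intermediate filament vimentin, from 273 ± 8.0 to 71.4 ± 3.7 (log2 -1.92). The actin-binding tropomyosin TPM4 (ENSG00000167460, chromosome 19) rose from 30.6 ± 0.96 to 108.8 ± 3.4 FPKM, 3.56-fold higher (log2 1.80, SE 0.040, adjusted p = 1.98e-06).

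In all, 5068 of 13365 tested genes (37.9%) changed, 2355 of them higher and 2713 lower in siHJURP. Of these, 173 changed at least 2-fold, 47 higher and 126 lower, a count that was 303 with a pseudocount of 0.1 and 331 with voom. The median size of the log2 fold change of changed genes was 0.33. The balance of higher and lower genes moved with the scaling. Lower genes were 53.5% of the changed genes in the deposited FPKM, 40.5% after rescaling to TPM (3155 higher, 2144 lower) and 41.5% with each library's own read total (3102 higher, 2198 lower). The 3 values of each group did not overlap for 6975 tested genes (52.2%), where chance gives 10%.

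Among the other genes with the lowest fold changes were SZRD1 (59.9 ± 1.7 to 15.6 ± 0.33 FPKM, log2 -1.88), G0S2, an inhibitor of triglyceride breakdown (log2 -1.83), and EMP1, an epithelial membrane protein (log2 -1.82). GPAT3, an acyltransferase of glycerolipid synthesis, KDELC2, ANPEP, which encodes aminopeptidase N, and TRNP1 had log2 fold changes of -1.76, -1.74, -1.73 and -1.71. On the higher side, GANAB, the catalytic subunit of glucosidase II, rose from 49.5 ± 1.4 to 139.4 ± 1.2 FPKM (log2 1.47, SE 0.035). OGFR, a receptor for opioid growth factor, rose by 1.37 on the log2 scale, ZNF664, a zinc finger protein, by 1.36, and HABP4, a hyaluronan-binding protein, by 1.32. OGFR, ZNF664, HABP4 and VIM overlap other tested genes, whose reads could not be told apart from theirs.

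The highest fold changes also held 4 short RNA genes with few reads. MT-TF, a mitochondrial tRNA, had 0 or 1 reads per NC library and 4 or 5 per siHJURP library (log2 1.83), and RNU6-126P had 0 or 1 and 3 to 7 (log2 1.32). RNU7-159P had 0 or 1 reads in NC and 2 to 8 in siHJURP (log2 1.80, adjusted p = 0.0173). Its call was lost without NC replicate 1 (0.055) and without NC replicate 2 (0.0539). RNA5SP412 had 1 to 4 reads in NC and 7 to 17 in siHJURP (log2 1.51, adjusted p = 0.0173), and its call was lost without NC replicate 2 (0.0543) and without NC replicate 3 (0.0563). RNA5SP412 and RNU6-126P lie inside longer genes on the same strand.

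**Figure D1:**
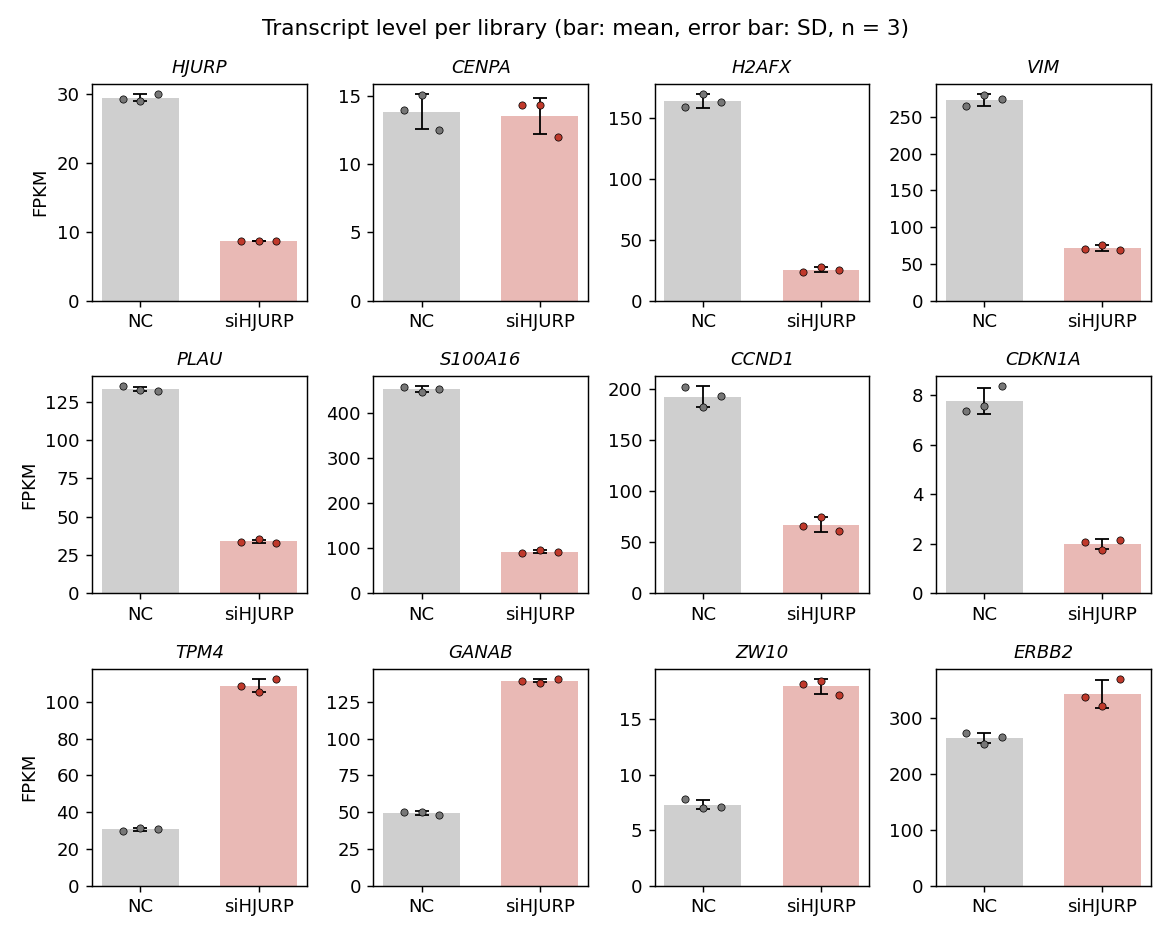
FPKM of 12 genes in NC (grey) and siHJURP (red), with each point a library, each bar the mean and each error bar the SD (n = 3). HJURP lies at 8.64 to 8.66 FPKM in the siHJURP libraries, against a mean of 29.4 in NC.

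Genes of DNA replication were lower together. Of 50 tested genes of the G1/S transition and DNA replication, 32 fell, 0 rose and 18 did not pass, with a median log2 fold change of -0.23. UHRF1, which recruits the maintenance DNA methyltransferase, fell from 23.1 ± 0.19 to 15.2 ± 0.52 FPKM (log2 -0.57). The replication licensing factor CDT1 and the helicase subunit MCM4 each fell by 0.45 on the log2 scale, and the flap endonuclease FEN1 by 0.40. Adjusted over the list alone, 35 fell. The list stood apart from other genes at a preset correlation (camera adjusted p = 8.15e-09), but not with an estimated correlation (adjusted p = 0.395).

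Of 38 genes of homologous recombination and Fanconi anaemia repair, 16 fell and 3 rose (17 and 3 adjusted over the list alone), with a median of -0.11. RMI1, of the complex that dissolves recombination intermediates, fell by 0.57 on the log2 scale, the nuclease-helicase DNA2 by 0.46 and FANCA by 0.39. Camera gave an adjusted p of 0.0469, and it was 0.426 with an estimated correlation. The call was lost without NC replicate 1 (0.0623), without siHJURP replicate 1 (0.0528) and without siHJURP replicate 3 (0.0734), and without siHJURP replicates 1 and 3 together (0.123). It was also lost with no intensity trend (0.0654), with protein-coding genes alone (0.0722), with a replicate block (0.058) and with voom (0.0674).

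Among 16 genes of the cyclin D, CDK and CDK inhibitor list, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.22. CDKN1A, the CDK inhibitor p21, fell from 7.75 ± 0.52 to 1.99 ± 0.20 FPKM (log2 -1.55), and CCND1, cyclin D1, fell from 193 ± 9.9 to 67.3 ± 7.0 FPKM (log2 -1.51). E2F4 and E2F3, transcription factors of the cell cycle, fell by 0.43 and 0.33. Against other genes, camera gave an adjusted p of 0.0119, and 0.376 with an estimated correlation. With a filter at a mean FPKM of at least 5 the call was lost (0.115, median -0.20).

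Immediate early and MAPK feedback genes, which report signalling through the MAP kinases, had one of the lowest medians. Of 31 members, 26 fell, 2 rose and 3 did not pass, and the median was -0.52. Adjusted over the list alone the counts were also 26 and 2. SPRY4, a feedback inhibitor of the pathway, fell from 8.43 ± 1.1 to 2.70 ± 0.18 FPKM (log2 -1.34), and FOSL1, a subunit of AP-1, from 167 ± 8.7 to 66.5 ± 5.3 (log2 -1.32). IER3 fell by 0.57 on the log2 scale. In the camera test the adjusted p was 8.85e-09, and 0.184 with an estimated correlation.

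Of 19 genes of NF-kB and inflammatory cytokines, 14 fell and 0 rose, with a median of -0.57. The chemokine CXCL8 fell from 61.0 ± 2.0 to 23.4 ± 0.73 FPKM (log2 -1.34), and the cytokine CSF1 fell by 1.05 on the log2 scale. TNFAIP2 fell by 0.69 and NFKBIZ, a nuclear regulator of NF-kB, by 0.68. Adjusted over the list alone, 14 fell and 1 rose. At the preset correlation camera gave an adjusted p of 7.2e-06, and 0.376 with an estimated correlation.

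Of 37 genes of epithelial-mesenchymal transition and matrix, 20 fell and 3 rose (22 and 4 adjusted over the list alone), with a median of -0.33. Beside PLAU and VIM, the metalloproteinase inhibitor TIMP1 fell from 94.6 ± 3.2 to 42.7 ± 3.0 FPKM (log2 -1.13), and COL4A1, a basement membrane collagen, fell by 0.84 on the log2 scale. Camera gave an adjusted p of 6.71e-05, and 0.184 with an estimated correlation. Of 25 YAP/TAZ targets, 16 fell and 3 rose (16 and 4 adjusted over the list alone), with a median of -0.22. GADD45A fell by 1.05 on the log2 scale, F3, which encodes tissue factor, by 0.66 and CTGF by 0.44. Against other genes, camera gave an adjusted p of 0.00146, and 0.376 with an estimated correlation.

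Of 33 genes of hypoxia and glycolysis, 17 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -0.18. ANGPTL4, an inhibitor of lipoprotein lipase, fell by 1.43 on the log2 scale, NDRG1 by 0.93, the glucose transporter SLC2A1 by 0.89 and the glycolytic enzyme PGK1 by 0.86. In the camera test the adjusted p was 0.00137, and 0.463 with an estimated correlation. Of 36 MYC targets and genes of ribosome biogenesis, 15 fell and 2 rose (19 and 2 adjusted over the list alone), with a median of -0.16. MYC fell from 34.8 ± 0.59 to 25.2 ± 1.3 FPKM (log2 -0.45), PNO1 fell by 0.70 and LYAR by 0.62, while NOLC1, a nucleolar phosphoprotein, rose by 1.03. At the preset correlation camera gave an adjusted p of 0.00538, and 0.487 with an estimated correlation. The call of the MYC list was lost without siHJURP replicates 1 and 3 together (0.0843).

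Of 79 cytosolic ribosomal proteins, 25 fell and 0 rose, with a median of -0.13. RPL5 fell by 0.56 on the log2 scale, and RPL22 and RPL9 each fell by 0.26. Ribosomal protein genes have near-identical pseudogenes, so the split of their reads is uncertain. Adjusted over the list alone, 11 fell. Camera gave an adjusted p of 8.02e-05, and 0.658 with an estimated correlation. The call was lost without siHJURP replicates 1 and 3 together (0.104) and by fry (0.114). The lower count was 11 after rescaling to TPM, 8 with total reads and 7 after quantile scaling, where the median was -0.01 and the adjusted p was 0.46.

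Of 31 genes of the ATF4 and amino acid stress response, 15 fell and 4 rose, also when adjusted over the list alone, with a median of -0.24. The growth factor VEGFA fell by 0.98 on the log2 scale, the amino acid transporter SLC38A2 by 0.51 and the transcription factor CEBPB by 0.49. Against other genes, camera gave an adjusted p of 0.0362, and 0.376 with an estimated correlation. The call was lost without NC replicate 2 (0.0508, median -0.11), after quantile scaling (0.146, median -0.06) and with a filter at a mean FPKM of at least 5 (0.236, median -0.10). Of 24 genes of the TGF-beta and BMP response, 10 fell and 3 rose, also when adjusted over the list alone, with a median of -0.12. ID1 fell by 0.66 on the log2 scale, SMAD3, a transducer of TGF-beta signals, by 0.52 and TGIF1 by 0.50. In the camera test the adjusted p was 0.0362, and 0.376 with an estimated correlation. That call was lost without NC replicate 2 (0.0508), without siHJURP replicate 2 (0.0607), with protein-coding genes alone (0.0506) and with the filter at 5 (0.115).

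Of 13 markers of ovarian carcinoma and the SKOV3 line, 5 fell and 2 rose, also when adjusted over the list alone, with a median of -0.24. The transcription factor SOX17 fell from 22.1 ± 1.3 to 11.1 ± 0.36 FPKM (log2 -0.93), the keratin KRT18 fell by 0.85 and PAX8 by 0.27. ERBB2, the receptor HER2, rose from 264 ± 9.7 to 343 ± 25 FPKM (log2 0.37, adjusted p = 0.00299). At the preset correlation camera gave an adjusted p of 0.0419, and 0.376 with an estimated correlation. The call of the list was lost without NC replicate 2 (0.0508) and without siHJURP replicate 2 (0.0642). It was also lost with a filter at a mean FPKM of at least 5 (0.053), with no intensity trend (0.0532), with array weights (0.0528) and with protein-coding genes alone (0.0538).

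Genes of sterol and fatty acid synthesis were higher, with 15 of 31 rising, 4 falling and a median of 0.21. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose from 8.93 ± 1.0 to 19.8 ± 1.9 FPKM (log2 1.06). The enzymes PMVK and SC5D rose by 0.72 and 0.63, and MSMO1 fell by 0.78. Adjusted over the list alone, 16 rose and 5 fell. Camera gave an adjusted p of 0.00808, and 0.487 with an estimated correlation. Of 33 genes of the proteasome and ubiquitin, 12 rose and 1 fell, also when adjusted over the list alone, with a median of 0.06. The proteasome ATPase PSMC3 rose by 0.49 on the log2 scale, PSMD13 by 0.27 and PSMC4 by 0.26. Against other genes, camera gave an adjusted p of 0.0276, and 0.658 with an estimated correlation. It was lost without NC replicate 1 (0.0506), without siHJURP replicate 2 (0.0913) and by fry (0.0653).

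Most type I interferon response genes were high in siHJURP replicates 1 and 3 and not in replicate 2. Of 36 tested members, 33, 8 and 34 lay above the highest NC library in siHJURP replicates 1, 2 and 3, and 17, 0 and 22 above 2 times that value. The 8 of replicate 2 held IFIT1 (3.12 against 2.38 FPKM), DHX58 (1.38 against 0.77), BST2 (66.4 against 57.2) and STAT2 (11.7 against 10.6). IFI6, an interferon-induced protein, had 160, 12.7 and 234 FPKM in siHJURP replicates 1, 2 and 3, against 13.9 to 16.9 in NC. ISG15, a ubiquitin-like protein induced by interferon, had 124 and 198 in replicates 1 and 3, against 16.6 to 21.1 in NC. The median of the 36 tested members relative to the NC mean was 0.89, -0.07 and 1.23 in siHJURP replicates 1, 2 and 3. HJURP had 8.66, 8.64 and 8.65 FPKM in the same libraries. IFNB1 and IFNL1, which encode interferons, had 0 reads in all 6 libraries.

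As a group of 3, the siHJURP libraries gave 6 higher and 1 lower member of the interferon list, a median of 0.68 and a camera adjusted p of 0.00092 (0.658 with an estimated correlation, and 0.242 by fry). Adjusted over the list alone, 0 rose and 0 fell. IFIT1, which binds viral RNA, rose from 2.0 ± 0.37 to 15.1 ± 11 FPKM (log2 2.07, SE 0.62, adjusted p = 0.0371). This call was lost without NC replicate 1 (0.0945), 2 (0.0738) or 3 (0.0868), and without siHJURP replicate 1 (0.113) or 3 (0.0971). BST2, the antiviral tetherin, rose from 51.9 ± 4.7 to 136.8 ± 64 FPKM (adjusted p = 0.0293), a call lost without NC replicate 1 (0.0783), 2 (0.0732) or 3 (0.0601), and without siHJURP replicate 1 (0.0929) or 3 (0.0749). STAT2, a transcription factor of the interferon response, rose by 0.56 (adjusted p = 0.026), a call lost without NC replicate 1 (0.0529), 2 (0.0756) or 3 (0.0578), and without siHJURP replicate 1 (0.0844) or 3 (0.0699). DHX58, a sensor of double-stranded RNA, rose by 1.28 (adjusted p = 0.0166), a call lost without NC replicate 1 (0.0512) and without siHJURP replicate 1 (0.0601).

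**Figure D2:**
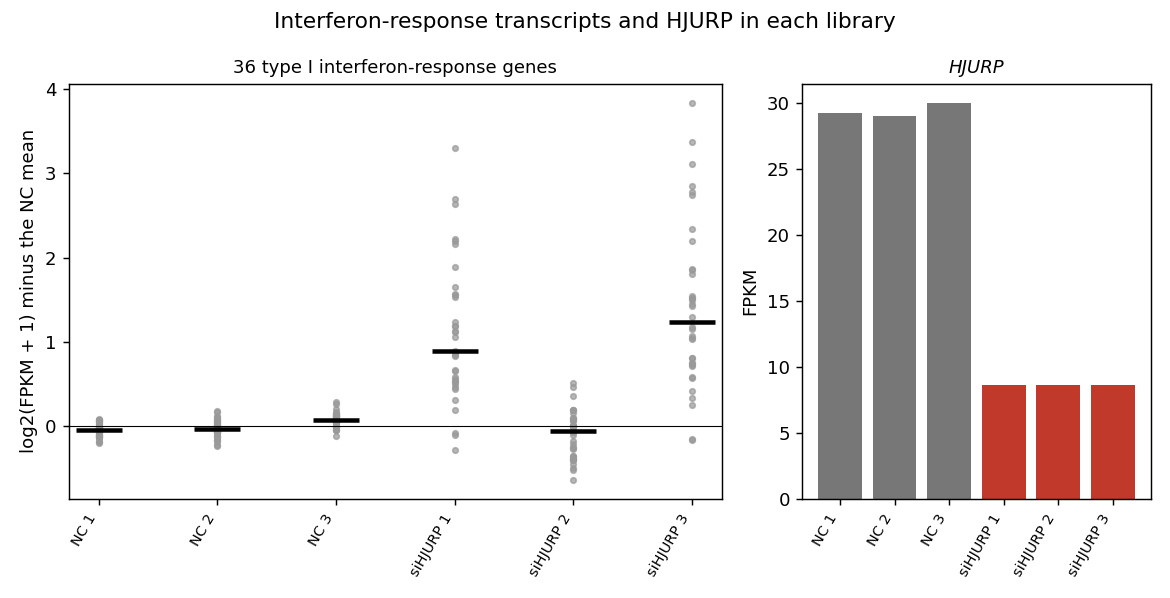
Left, log2(FPKM + 1) of the 36 tested interferon-response genes in each library minus their NC mean, with each point a gene and each line the median, and right, HJURP FPKM per library. The medians of siHJURP replicates 1, 2 and 3 lie at 0.89, -0.07 and 1.23, while HJURP lies at 8.66, 8.64 and 8.65 FPKM.

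Genes of mitosis and of the centromere did not move one way. Of 41 centromere and kinetochore genes, 4 rose and 10 fell, also when adjusted over the list alone (median -0.08, camera adjusted p = 0.403, and 0.781 with an estimated correlation). The counts were 7 and 10 under TPM and quantile scaling and 8 and 9 with total reads. ZW10, of the kinetochore complex that recruits dynein, rose from 7.32 ± 0.43 to 18.0 ± 0.68 FPKM (log2 1.19), CENPF by 0.58 on the log2 scale and SKA2 by 0.53. Of 48 genes of G2/M and mitosis, 7 rose and 14 fell, also when adjusted over the list alone (median -0.05, camera adjusted p = 0.195, and 0.755 with an estimated correlation), and the median was above 0 under TPM, total-read and quantile scaling, with 9 higher in each and 10, 10 and 9 lower. With no filter on low FPKM the G2/M list passed as lower (0.0421). PSRC1 fell by 0.82 on the log2 scale, the mitotic kinesin KIF11 by 0.51 and the kinase AURKA by 0.44. The proliferation marker MKI67 had 43.9 ± 5.6 and 43.5 ± 2.6 FPKM (adjusted p = 0.952), and CCNB1, cyclin B1, had 99.98 ± 4.1 and 99.2 ± 4.9 (adjusted p = 0.874). Neither passed the test, and the sign of both small differences turned under TPM, quantile and total-read scaling.

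Genes of the damage response went both ways. Of 22 genes of the damage checkpoint and WEE1 axis, 4 rose and 9 fell (4 and 10 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.155, 0.0295 with no filter on low FPKM, and 0.658 with an estimated correlation). The lower count was 6 under TPM and with total reads and 7 after quantile scaling. WEE1, the kinase that restrains CDK1, fell from 14.9 ± 0.22 to 10.2 ± 0.11 FPKM (log2 -0.51, adjusted p = 9.86e-05), and the kinase TLK2 rose by 0.72. CHEK1 had 10.8 ± 0.50 and 9.55 ± 0.49 FPKM and passed by little (log2 -0.16, adjusted p = 0.0496). Its call was lost without NC replicate 1 (0.0536), 2 (0.0884) or 3 (0.144) and without siHJURP replicate 1 (0.141) or 3 (0.14), and also under TPM (0.134), total-read (0.13) and quantile (0.0953) scaling. The same call was lost with a replicate block (0.0817), with no intensity trend (0.0676) and with no filter on low FPKM (0.115).

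Of 31 apoptosis regulators, 10 fell and 5 rose (10 and 6 adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.36, and 0.59 with an estimated correlation). Under TPM, total-read and quantile scaling 9 fell and 7 rose, with a median of 0.02, 0.01 and -0.01. TNFRSF1A, a receptor of tumour necrosis factor, fell from 26.9 ± 0.57 to 17.9 ± 0.48 FPKM (log2 -0.57), and the death receptor TNFRSF10B fell by 0.92 on that scale. Of 37 other DNA repair genes, 9 rose and 6 fell (9 and 7 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.318, and 0.487 with an estimated correlation), among them the glycosylase NEIL3, which fell by 0.73. The repair counts were 12 and 3 under TPM (median 0.15), 13 and 3 with total reads (0.12) and 9 and 4 after quantile scaling (0.09).

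Further lists did not pass in the main fit either. Of 11 replication-dependent histones, 2 fell and 0 rose, also when adjusted over the list alone (median -0.25, camera adjusted p = 0.0835, and 0.376 with an estimated correlation). This list passed without siHJURP replicate 3 (0.0411), with no filter on low FPKM (0.0241) and under TPM (0.0495), total-read (0.0478) and quantile (0.0481) scaling. The 2 genes were the linker histone HIST1H1C (log2 -0.68) and HIST2H2BE (log2 -0.37, adjusted p = 0.0245). The call of HIST2H2BE was lost without NC replicate 1 (0.0829) or 2 (0.0629) and without siHJURP replicate 1 (0.0619), 2 (0.059) or 3 (0.0623). The same call was lost with a replicate block (0.056) and with no filter on low FPKM (0.0699). Of 27 endoplasmic reticulum chaperones, 6 rose and 7 fell (7 and 8 adjusted over the list alone), with a median of 0.01 (camera adjusted p = 0.902, and 0.906 with an estimated correlation). Under TPM and with total reads 7 rose and 5 fell, and after quantile scaling 7 and 6. CRELD1 rose by 0.75 and DNAJB11 fell by 0.45. Of 20 genes of the cytosolic heat shock response, 5 rose and 3 fell (6 and 3 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.36, and 0.658 with an estimated correlation). With other scalings 7 (TPM, total reads) or 9 (quantile) rose and 2 fell. HSP90AA1, an HSP90 chaperone, rose by 0.40 and the co-chaperone BAG3 fell by 0.27.

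Of 29 genes of the NRF2 and oxidative stress response, 5 rose and 9 fell, also when adjusted over the list alone (median -0.02, camera adjusted p = 0.539, and 0.781 with an estimated correlation). The counts were 7 and 8 under TPM, 7 and 7 with total reads and 9 and 7 after quantile scaling, with a median above 0 in each. ME1, the malic enzyme, rose by 0.86 on the log2 scale and OSGIN1 fell by 0.77. Of 56 nuclear-encoded genes of oxidative phosphorylation, 7 rose and 4 fell (2 and 0 adjusted over the list alone). Their median was -0.03 while camera placed them higher (adjusted p = 0.999, and 1 with an estimated correlation). The median was above 0 under TPM (11 higher, 3 lower), total-read (11 and 3) and quantile (9 and 3) scaling. SDHC, a subunit of succinate dehydrogenase, rose by 0.23. Of 13 mitochondrially encoded genes, 1 rose and 0 fell, and 0 did so adjusted over the list alone (median 0.05, camera adjusted p = 0.374, and 0.781 with an estimated correlation). Under TPM and quantile scaling 3 rose, and 2 with total reads. In the main fit it was MT-ATP8 (log2 0.40, adjusted p = 0.0183), whose call was lost without siHJURP replicate 1 (0.0519) and without siHJURP replicate 2 (0.0536).

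Of 19 genes of platinum transport and detoxification, 6 fell and 0 rose, also when adjusted over the list alone (median -0.08, camera adjusted p = 0.105, 0.0295 with no filter on low FPKM, and 0.376 with an estimated correlation). The lower count was 4 under TPM and with total reads and 5 after quantile scaling. The metallothionein MT2A fell by 1.13 on the log2 scale and the channel subunit LRRC8A by 0.59. Of 37 splicing factors, 4 rose and 12 fell, also when adjusted over the list alone (median -0.05, camera adjusted p = 0.268, and 0.755 with an estimated correlation), with SF3B2 higher by 0.69 and SRSF4 at -0.27. The lean of the splicing factors to lower calls was not kept under TPM (8 higher, 7 lower), with total reads (6 and 5) or after quantile scaling (8 and 6), where the median lay within 0.01 of 0. Of 13 genes of the RNA interference machinery, 2 rose and 3 fell, also when adjusted over the list alone (median -0.05, camera adjusted p = 0.405, and 0.781 with an estimated correlation). Under TPM, total-read and quantile scaling the counts were the same, with medians of 0.005, -0.0007 and -0.01. DROSHA rose by 0.35, and TNRC6A, AGO2, the Argonaute that cleaves targets, and DGCR8 fell by 0.60, 0.58 and 0.23. Of 22 transcripts sensitive to nonsense-mediated decay or intron retention, 2 rose and 8 fell (3 and 10 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.13, 0.0275 with no filter on low FPKM, and 0.526 with an estimated correlation). GADD45B fell by 0.85, and the nuclear RNAs NEAT1 and MALAT1 rose by 0.57 and 0.34.

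Of the 32 lists tested, 16 passed with camera at the preset correlation, 13 lower and 3 higher. With an estimated correlation 0 passed, where the smallest adjusted p was 0.184, and fry called 20. The epithelial-mesenchymal, ATF4 and ovarian marker lists had estimates of 0.00476, -0.0172 and -0.0229, below the preset 0.01. A higher correlation therefore does not account for the loss of their calls. The other lists that passed had estimates above 0.01, up to 0.933 in the interferon list. Calls within the lists that passed moved with the scaling too. Under TPM the count of higher genes went from 1 to 4 in the hypoxia list, from 2 to 5 in the MYC list, from 3 to 6 in the epithelial-mesenchymal list, from 3 to 5 in the YAP/TAZ and TGF-beta lists and from 6 to 9 in the interferon list. After quantile scaling it went from 12 to 19 in the proteasome list (median 0.16), and the hypoxia list had a median of -0.06. With total reads the homologous recombination list had 5 higher genes and a median of -0.06. Of the markers of other cell types, only KDR, a receptor of endothelial cells, reached the level for testing, with 1.15 to 1.48 FPKM in NC and 0.52 to 0.71 in siHJURP.

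**Figure D3:**
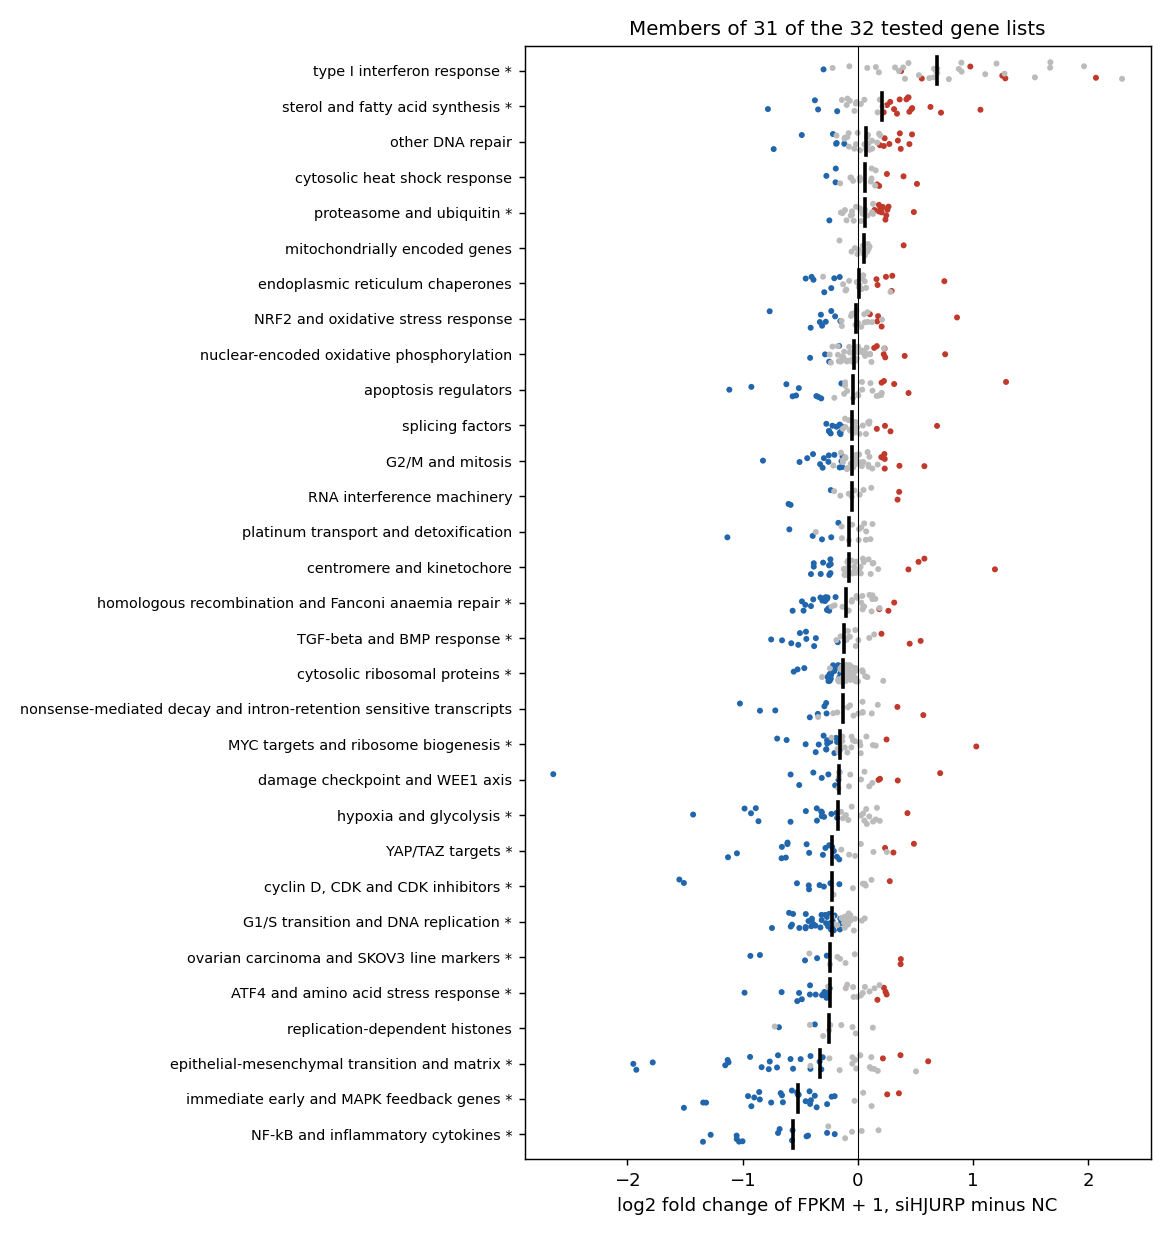
Log2 fold change of FPKM + 1 (siHJURP minus NC) of the members of 31 of the 32 tested lists, with each point a gene (red higher, blue lower, grey not past the test), each line the median, and a star on the 16 lists past camera at the preset correlation. The NF-kB list has the lowest median, -0.57, and the interferon list the highest, 0.68.

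The genes that fell held certain short sequences in their 3′ UTR more often than other genes, in a scan made after the data were seen. CCAGCAA had the lowest score of all 16384 7-mers (z = -9.63), and the 1751 genes with it had a median log2 fold change of -0.06 against 0.00 in the others. H2AFX, PLAU, VIM, SZRD1, EMP1 and GPAT3, among the 12 lowest genes, held it. To test sequences on genes that had not served to pick them, they were picked in the odd-numbered chromosomes with X and counted in the even-numbered ones, and the other way round. The 4 lowest were CCAGCAA, CAGCAAA, ACCTTCC and CCTTCCA in both sets. Of the 97 scanned genes that fell at least 2-fold, 65 (67.0%) held one of them, against 39.7 in draws of genes of the same set with UTRs of like length (highest of 1000 draws 54). In the odd-numbered set alone it was 36 of 53 (highest draw 31), and in the even-numbered set 29 of 44 (highest draw 30). The highest scores were those of CGGAGAA (z = 7.49) and TCGGAGA (z = 6.30). TPM4 held both and HABP4 held TCGGAGA. The named genes did not sort cleanly by these sequences. TPM4 also held CAGCAAA, and GANAB, ZNF664 and IFIT1, which rose, held CCTTCCA. SZRD1, which fell, held TCGGAGA beside CCAGCAA. The 2 highest were CGGAGAA and TCGGAGA in the odd-numbered set and CGGAGAA and GGAGAAT in the even-numbered one. Of 30 scanned genes that rose at least 2-fold, 12 held one picked in the other set, against 4.07 in such draws (highest 9). By set it was 8 of 18 in the odd-numbered (highest draw 9) and 4 of 12 in the even-numbered (highest draw 4).

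Without the genes that held CCAGCAA, CAGCAAA, ACCTTCC, CCTTCCA, CGGAGAA or TCGGAGA in the 3′ UTR, 2296 of 8308 tested genes changed, 1189 higher and 1107 lower. Of these 8308 genes, 2707 had passed in the main fit, so part of the lower count follows from the new fit and adjustment. Among scanned genes, 46.7% with one of these sequences and 39.1% without had passed in the main fit. The ATF4 list then lost its call (adjusted p = 0.591), with a median of -0.04 over 15 members against -0.24 over all. So did the cyclin D (0.195, -0.10 against -0.22), hypoxia (0.138, -0.05 against -0.18) and TGF-beta (0.27, -0.05 against -0.12) lists. The proteasome list lost its call too (0.0866), but its median did not shrink, at 0.09 over 24 members against 0.06 over all 33. The centromere and kinetochore list gained a call as lower (0.0457), with a median of -0.08 over 28 members, as over all 41. The immediate early and MAPK feedback list kept its call (3e-06), with a median of -0.52 over its 14 members without these sequences. Of the other lists that kept their calls, the epithelial-mesenchymal list (0.00735) had a median nearer 0, -0.18 over 18 members against -0.33 over all, and the homologous recombination list (0.00735) one further from 0, -0.16 over 24 against -0.11.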

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

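The fits with voom, total-read scaling, genes of at least 200 bases, siHJURP replicates 1 and 3 left out, and genes with the 3′ UTR sequences left out were chosen after seeing the data. HJURP kept its direction and its call in each alternative, with a log2 fold change of -1.67 to -1.64 when 1 library was left out. Over those 6 fits, 3719 to 4724 genes changed, 1649 to 2192 higher and 2070 to 2532 lower, 161 to 204 at least 2-fold, and 13 to 17 lists passed. The count of genes changed at least 2-fold was 303 with a pseudocount of 0.1 and 331 with voom, scales that shrink low genes less. Without siHJURP replicates 1 and 3, where the lone sample is assumed to vary like the others, 1844 genes changed, 716 higher and 1128 lower. The interferon list then had a median of -0.066, CENPA 0.048 and CCNB1 0.060. Without the genes that hold the 3′ UTR sequences, where fewer genes were tested, 2296 changed, 1189 higher and 1107 lower, 86 of them at least 2-fold. With an estimated correlation 0 lists passed.

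Small differences that did not pass the test turned sign. Under TPM the log2 fold change was 0.026 for CENPA, 0.048 for CCNB1 and 0.051 for MKI67. With total reads it was 0.019 for CENPA, 0.042 for CCNB1 and 0.045 for MKI67. After quantile scaling it was 0.011 for CENPA, 0.10 for CCNB1, 0.059 for MKI67 and 0.061 for MT-ND3, and with array weights 0.024 for CENPA. Total-read scaling shifts genes alike by 0.055 between the groups and TPM by 0.060, and these 3 genes moved by 0.051 to 0.054 and by 0.057 to 0.060, so those turns follow from the scaling itself. The cause under quantile scaling and array weights was not tested. When 1 library was left out they ranged from -0.098 to 0.048 for CENPA, -0.048 to 0.022 for CCNB1 and -0.12 to 0.057 for MKI67.

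With a replicate block 4527 genes changed, 2050 higher and 2477 lower, 176 at least 2-fold, and 15 lists passed. The deviations of same-numbered libraries within their groups had correlations of 0.0025, -0.0116 and 0.0163 with each other. The replicate numbers were therefore not taken to pair the samples. Over 141 genes of the rule and all alternatives, 3026 of 3151 values kept direction and side of the threshold, 85 lost the call, 19 gained one and 21 turned. Over the lists, 720 of 798 did, 51 lost the call, 26 gained one and 1 turned. Depth limits the short RNA genes, which had 17 reads or fewer per library.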

Other observations

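The gene families and EGFR below, and all tests of families, were chosen after the results were seen. Of 132 families of genes that share the stem of their symbol and have at least 10 tested members, 9 passed with camera, 4 higher and 5 lower. With an estimated correlation 0 passed, where the smallest adjusted p was 0.685. The TNFRSF and VPS stems had estimates of -0.0402 and 0.00367, below the preset 0.01, so a higher correlation does not account for their loss. The other families that passed had estimates above 0.01. Nucleoporins, which build the nuclear pore, were lower, with 13 of 21 falling and 0 rising (median -0.23, camera adjusted p = 0.00452). NUP43 fell from 26.9 to 12.9 FPKM (log2 -1.01, SE 0.063), NUP50 by 0.69 on the log2 scale and NUP153 by 0.63. Of 11 KLF transcription factors, 9 fell and 1 rose (median -0.37, camera adjusted p = 0.0191), with KLF10 at -0.52 and KLF11 at -0.45. Of 10 TNF receptors, 7 fell and 0 rose (median -0.36, camera adjusted p = 0.0216). TNFRSF10D, a decoy receptor for TRAIL, fell from 16.1 to 5.64 FPKM (log2 -1.37, SE 0.077). Of 10 keratins, 7 fell and 1 rose (median -0.41, camera adjusted p = 0.0291), with KRT81 at -0.72 and KRT17 higher by 0.50. The RPS stem, which holds ribosomal proteins and kinases, was also lower (median -0.12, camera adjusted p = 0.0283).

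On the higher side, 149 of 411 zinc finger genes with the stem ZNF rose and 29 fell (median 0.12, camera adjusted p = 4.96e-05), with ZNF629 higher by 0.85 and ZNF639 lower at -0.85. Of 13 genes of intraflagellar transport, which builds cilia, 9 rose and 0 fell (median 0.28, camera adjusted p = 0.00647). IFT81 rose from 4.38 to 6.75 FPKM (log2 0.53, SE 0.043) and IFT140 from 2.46 to 3.98 (log2 0.52, SE 0.061). The PHF family (8 of 17 higher, median 0.22, camera adjusted p = 0.0342) and the VPS family of vesicle sorting (12 of 35 higher, 4 lower, median 0.14, camera adjusted p = 0.0443) were higher too. Each of the 9 medians kept its sign with total-read scaling, with the lower ones nearer 0 (RPS at -0.07) and the higher ones further from it. EGFR, a receptor upstream of the MAP kinases, fell from 32.3 ± 2.3 to 11.6 ± 0.51 FPKM (log2 -1.39, SE 0.060, limma adjusted p = 2.21e-05).

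For the patterns below, the scan itself and the tests of site location, letter order, genes without the sequences, MAPK members, labelling, other cells and the degree of silencing were chosen after the results were seen. The tests of TGTCACG and the 13-base sequence had their predictions written before their values were seen. A test of site location written beforehand was dropped, because it used sequences picked from the same genes. The genes that fell may in part be targets of the HJURP siRNA through short matches in the 3′ UTR. CCAGCAA (z = -9.63) lay 5.27 below the next lowest of the 140 orderings of its letters (-4.36), and when fold changes were permuted and the lowest 7-mer picked anew this gap was at most 2.70 in 1000 runs, which argues against base composition alone. With the 7-mer picked in the odd-numbered chromosomes with X and tested in the even-numbered ones, and the other way round, CCAGCAA was picked both times. Genes with it in the 3′ UTR then had a median that differed by -0.037 from that of genes with it in the coding sequence only (mean of both sets, permutation p = 0.00042, with -0.027 and p = 0.0399 in the odd-numbered set and -0.047 and p = 0.00478 in the even-numbered one), as such pairing predicts. Unlike the scan, these medians were not corrected for UTR length, so the test cannot tell site location apart from UTR length. Genes with CCAGCAA in the coding sequence only also lay below genes without it (-0.03 against 0.01, p = 1e-05, the smallest that 100000 permutations can give). In all scanned genes, which had served to pick them, the UTR sites differed from coding-only sites by -0.036 for ACCTTCC (permutation p = 0.00139). The difference was -0.024 for CAGCAAA (permutation p = 0.0133). For CCTTCCA it was -0.008 and did not pass (permutation p = 0.441), so the prediction was not met there. Coding-only genes of CCTTCCA lay below genes without it (-0.025 against 0.005, permutation p = 0.00036). The 5 lowest-scoring 7-mers all lie in ACCTTCCAGCAAA, which sits in the coding sequence of HJURP (chromosome 2, 233841307 to 233841319, hg38, exon 8 of ENST00000411486.6) and in 2 of the 10835 scanned genes, HJURP and PTAR1 (log2 -0.27). Any sequence of this length is rare (100 other orderings of its letters lay in at most 3 genes each). The count of 2 was therefore bound to be low, as the prediction against a chance match asked, and decides nothing. That HJURP, the gene that the design names, holds it was seen before the test and remains an observation. Whether it is the siRNA's target is untested, because the siRNA sequence was not given in the sources used here. Within it, ACCTTCC and CCTTCCA lie at the start, and CCAGCAA and CAGCAAA at the end. Pairing through a single 7-base stretch would therefore not account for all of them. Loss of HJURP stays open. It cannot be told apart by the 2260 changed genes among 5778 scanned genes without the left-out 7-mers in the 3′ UTR, since they may follow either cause indirectly. The 14 MAPK feedback members without these 7-mers there still had a median of -0.516 (against 0.01 in other such genes, permutation p = 1e-05). Of these 14, limma called 12 lower and 1 higher. The permutation shuffled genes, which may move together, so its p does not measure the spread between libraries. The median and these calls argue against direct pairing at these 7-mers in the 3′ UTR for that list. Sites in the coding sequence of these members were not examined.

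The genes that rose may in part be released from pairing by the control siRNA in the NC libraries. With the 6-mer picked in one of these sets and tested in the other, CGGAGA was picked both times. Genes with it in the 3′ UTR then had a median 0.026 above that of genes with it in the coding sequence only (mean of both sets, permutation p = 0.00546), as that explanation predicts. The difference was 0.037 in the odd-numbered set (permutation p = 0.00655) and 0.014 in the even-numbered one, where it did not pass (permutation p = 0.257), and coding-only genes also lay above genes without it (0.02 against -0.03, p = 1e-05). In all scanned genes, which had served to pick them, it was 0.041 for CGGAGAA (permutation p = 0.0187). For TCGGAGA it was 0.045 and did not pass (permutation p = 0.054). These medians were not corrected for UTR length either. CGGAGA and TGTCACG match the seeds of the 2 strands of a widely used control duplex, and whether it was used here was not given in the sources used here. Genes with TGTCACG differed by 0.026 from other genes (95% bootstrap interval -0.01 to 0.05, permutation p = 0.0669). The prediction written beforehand would have counted a p of 0.05 or more against the other strand, but that bound was wrong and was dropped after the value was seen, because the interval holds 0 and also differences up to 0.05, so the p decides neither way. The difference of 0.061 between genes with and without CGGAGA in the 3′ UTR lies outside the interval, and a smaller effect of this strand stays open.

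The interferon response of siHJURP replicates 1 and 3, which most members lacked in replicate 2, has no explanation that passed a test here. A wrong label of replicate 2 is argued against by a fit without that library, in which 133 genes other than HJURP were at least 2-fold lower, and replicate 2 lay below every NC library in 129 of them. Its HJURP was 8.64 FPKM, against a mean of 29.4 in NC. Of the markers of other cell types, 0 reached 1 FPKM in both replicates 1 and 3 and exceeded replicate 2. RGS5 came near this bound, with 1.22 and 1.04 FPKM in replicates 1 and 3, but had 1.08 in replicate 2. It had 0.68 to 0.87 in NC. The count of 0 argues against RNA from blood, endothelial or stromal cells at that level. It does not cover a smaller share of such cells or another epithelial line. A weaker silencing in replicate 2 is argued against by its HJURP FPKM, which differed by -0.197% from the mean of the others. A response to the transfected duplex that varied between cultures was not tested.

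The test of other splits was chosen after the results were seen. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split, 1 of the 10, gave 5068 changed genes, 2355 higher and 2713 lower, 173 at least 2-fold and 16 lists, and the highest of the others gave 0, 0, 0, 0 and 12. Each of the others placed libraries of both treatments in each group. The difference between siHJURP and NC then added to the spread within groups, and part of it also remained between them. The other splits therefore do not show what chance alone would call.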
